A study of Mus musculus with 16 samples.

How the data were processed

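RNA was measured in cerebellum and hippocampus of mice carrying a mutant Twinkle transgene and of wild-type mice. Total RNA was extracted with Trizol and 5 ug of it was turned into biotin-labelled cRNA for Affymetrix arrays, per the labels' protocols. GCOS 4.0 is named in the submitters' processing notes. The probe-level summary, the normalization between arrays and the centring of the values are not given in the sources used here. There were 16 arrays in 4 groups of 4, assigned to genotype, region and replicate number from the sample titles. The free-text description of the hippocampus samples names cerebellum, while their title, source and tissue entry all name hippocampus, which was followed. The labels call the replicates biological replicates and do not say which regions came from the same animal, so p-values measure the spread between these samples. The ages given ranged from 21 to 26 months, with replicates 1 and 2 at 24 months or more and replicates 3 and 4 at 23 months or less. The genotypes were not matched for age. In order of replicate number, wild types were 26, 24, 21 and 23 months old and mutants 24, 24, 21 and 21.

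The values deposited by the authors were on a log scale, taken here as log2, and were relative. For 99.9% of probe sets in each region, the median over the 8 arrays of that region lay within 1e-05 of 0. Each value is therefore a difference from the median array of its region, and no expression level is left. The log base is not stated. Base 10 was excluded because the widest probe set spanned 8.91 units, against 4.82 decades on a 16-bit scanner. If the base were e, every difference below would have to be multiplied by 1.44 to be on the log2 scale. The centring fixes the outcome of any comparison of hippocampus with cerebellum, so these 2 planned comparisons were not made. The number of arrays limits the precision. The median standard error of a genotype difference was 0.0741 in each region, 0.105 for the difference between regions and 0.0498 for the average over regions.

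Of 45101 probe sets, 64 controls were left out, and so were 133 others with an empty value. The empty values numbered 134, with 77 in wild-type cerebellum replicate 3 and 57 in wild-type hippocampus replicate 3. Of the 44904 probe sets analysed, 34843 had 1 gene symbol in the GEO platform annotation, 931 had several and 9130 had none. Genes were named only from probe sets with 1 symbol. The mean over a gene's probe sets gave 18168 genes, of which 9192 rested on 1 probe set. An identifier match to the gene table was found for 18008 genes and changed 0 symbols.

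Before the data were examined, a filter on dim probe sets, the brightest probe set per gene and a variance trend with expression had been planned. All need an expression level, so no filter was applied, the mean over probe sets was used and the variance model had no trend. limma 3.58.1 in R 4.3.3 was fitted to all 16 arrays with a mean per group and 12 residual degrees of freedom. It tested mutant against wild type in each region and the difference of these effects, hippocampus minus cerebellum. The average over regions was tested on 8 values, each the mean of both regions for a genotype and replicate number. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A difference is always mutant minus wild type on the log2 scale, with its standard error (SE); group values are mean ± SD.

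There were 44 gene lists, 24 for pathways and 20 for cell types, neighbouring tissues or sex, written down before the data were examined. Of these, 42 had at least 5 measured members and were tested with limma's camera at a preset correlation of 0.01, adjusted over the 42. An estimated correlation and limma's fry were the alternatives. fry asks whether a list's genes moved one way on balance and does not compare them with other genes. The rule for named genes was also fixed in advance. It took Twnk, the 12 genes of smallest p in each direction where fewer were called, 5 in each direction for the difference between regions, and 3 members of smallest p per list and region. Where a value is given for a gene outside it, the text says so.

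The fits were tested on simulated data with 200 changed genes among 18168. Of genes changed by 0.5 log2 units, 96% were recovered in the cerebellum, 80% in the hippocampus, 60% in the difference between regions and 100% in the average. At 0.25 units the shares were 26%, 34%, 8% and 60%. Each share rests on 50 genes, and both regions were simulated with the same spread per gene. The gaps between the regions therefore come from the random draw. False calls numbered 12 of 173, 8 of 165, 13 of 147 and 5 of 185. The noise was drawn independently for each gene and array, without the array-wide differences seen in the measured data. These shares and false calls therefore need not hold for the measured arrays. In the list test, 1 of 2 lists raised by 0.1 was called and 0 of 40 unchanged lists were. Its genes were drawn independently, while the measured lists had a median estimated correlation of 0.14 in each region. It therefore does not show how often unchanged lists of correlated genes are called.

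Alternatives fixed in advance were quantile normalization, median centring for genes, single probe sets, leaving out cross-hybridizing probe sets, array weights, age or the replicate set as a term, the replicate number as a block, a fit of 1 region alone and leaving out each replicate. Quantile normalization was run on the centred values of all 16 arrays together. The variance trend, planned for the main fit, was run as an alternative. Its covariate was the mean of centred values, which is not an expression level. Others, chosen after the data had been seen, were the probe set of largest spread per gene, leaving out the 40% of genes with the smallest spread, keeping probe sets with empty values, median centring for lists, all settings for lists in the difference, the average and the replicate sets, and leaving out arrays with raised markers of other tissue or shifted spike-in probe sets.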

Results

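Gene expression was compared between mice carrying mutant Twinkle and wild-type mice in the cerebellum and in the hippocampus, with 4 arrays per genotype and region. Twinkle, encoded by Twnk, is the helicase that unwinds mitochondrial DNA for replication. The mice, known as deletor mice, were made as a model of progressive external ophthalmoplegia, a disease with weakness of the eye muscles and deletions in mitochondrial DNA. The animals were 21 to 26 months old, and wild types of replicates 1 and 4 were older than mutants of the same number. Every value is relative to the median array of its region, so genes are described by differences between genotypes, and the number of arrays limits their precision.

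Twnk itself was measured by 1 probe set. In the cerebellum it lay at 0.03 ± 0.06 in mutants and -0.04 ± 0.07 in wild types (SD, n = 4), a difference of 0.06 (SE 0.05, limma adjusted p = 0.91), which was 0.03 without wild-type replicate 2 or without mutant replicate 3. In the hippocampus the values were 0.01 ± 0.02 and -0.05 ± 0.07 (SD, n = 4), a difference of 0.06 (SE 0.05, limma adjusted p = 0.77), which was 0.10 without wild-type replicate 4. Where this probe set lies relative to the transgene is not known here, so it checks neither the labels nor the overexpression.

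The comparison of genotypes in the cerebellum asked what mutant Twinkle did to gene expression there. Among genes higher in mutants, the smallest p belonged to 5430427O19Rik, at 0.33 (SE 0.06), and Nmi, which binds N-Myc and STAT proteins, at 0.38 (SE 0.08). Efcab7, a ciliary protein of Hedgehog signalling, was at 0.51 (SE 0.13) and Leo1, a subunit of the Paf1 complex, at 0.24 (SE 0.05). B3gnt8 lay at 0.36 and the exonuclease gene Trex2 at 0.26. Among genes lower in mutants, Alas2, the erythroid enzyme of haem synthesis, had the widest difference of those named, -0.97 (SE 0.24), with -0.24 ± 0.07 in mutants and 0.72 ± 0.48 in wild types (SD, n = 4). Slc25a31, a mitochondrial carrier of ADP and ATP, lay at -0.34 (SE 0.08), and Ogt, which adds N-acetylglucosamine to proteins, at -0.35 (SE 0.09). Gm10710 lay at -0.30. None of these genes passed, since each had an adjusted p of 0.88.

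limma called 0 of 18168 genes in the cerebellum. At an unadjusted p under 0.05 there were 979, against 908.4 by chance, and the smallest adjusted p was 0.884. Mutants and wild types lay fully apart for 447 genes, or 2.46%, where chance gives 2.86%. The count stayed at 0 under every alternative run.

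Several mitochondrial gene groups lay slightly higher in mutant cerebellum. For the mitochondrial ribosome, 61 of 65 measured members were above 0 with a mean of 0.08, led by Mrps35 at 0.24 and Mrpl32 at 0.17 (camera adjusted p = 1.1e-09; adjusted p = 0.71 with an estimated correlation). Subunits of respiratory complex I had 29 of 33 members above 0 and a mean of 0.06, with Ndufb3 at 0.13 (camera adjusted p = 0.00041; adjusted p = 0.71 with an estimated correlation), and a mean of 0.03 without wild-type replicate 2. Mitochondrial chaperones and proteases averaged 0.05, with 13 of 17 above 0 and Timm17a at 0.15 (camera adjusted p = 0.031; adjusted p = 0.71 with an estimated correlation). Their call was lost, at 0.04 each, without wild-type replicate 2, wild-type replicate 4 or mutant replicate 4, and Timm17a was at 0.08 without wild-type replicate 3. Beside these groups, the mean of the poly-A spike-in probe sets, which report on labelling, stood at 0.62 and 0.65 on mutant replicates 2 and 4 and at most at 0.05 on a wild-type array of the cerebellum. The mean of the hybridization spike-in probe sets stood at -0.724 on wild-type replicate 4 and 0.271 on wild-type replicate 3, and without the former the mitochondrial ribosome mean was 0.08. Without the mutant replicates 2 and 4 the means were 0.03 for the mitochondrial ribosome, 0.02 for complex I and 0.03 for chaperones, with camera adjusted p of 0.35, 0.46 and 0.46, and 0 of the 42 lists passed.

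Other lists lay lower in mutant cerebellum. Glycolysis genes averaged -0.06, with 15 of 18 below 0 and Eno2 at -0.17 (camera adjusted p = 0.0047; adjusted p = 0.71 with an estimated correlation). Synaptic vesicle and postsynaptic genes averaged -0.07, with 20 of 27 below 0, Dlg4 at -0.22 and Camk2b at -0.20 (camera adjusted p = 0.0035; adjusted p = 0.71 with an estimated correlation). Both calls were lost without wild-type replicate 3, where the means were -0.05 for glycolysis and -0.04 for synaptic genes and Eno2 was at -0.08. Circadian clock genes averaged -0.11, with 12 of 16 below 0, Per3 at -0.19 and Per2 at -0.35 (camera adjusted p = 0.0035; adjusted p = 0.67 with an estimated correlation). Choroid plexus genes averaged -0.31, with 21 of 22 below 0 (camera adjusted p = 0.0042; adjusted p = 0.88 with an estimated correlation), but the mean was -0.04 without mutant replicate 4, whose own mean was -1.03, and -0.17 without wild-type replicate 1, which ended the call too. The other 35 lists had means between -0.06 and 0.09. The stress response of amino acid and one-carbon metabolism, with Asns, Psat1 and Mthfd2 among its members, averaged 0.02 over 27 genes (camera adjusted p = 0.77). Adjusted over the list alone, 1 member of any list passed in the cerebellum, Alas2 in the blood cell list (adjusted p = 0.011 over that list). fry called 0 lists, and other divisions of the 8 arrays into 4 and 4 called a median of 5 and up to 12.

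The comparison of genotypes in the hippocampus put 7 genes under an adjusted p of 0.1, 4 of them higher in mutants and 3 lower. Arsj, which encodes an arylsulfatase, lay at -0.77 (SE 0.11, adjusted p = 0.057), with -0.28 ± 0.15 in mutants and 0.49 ± 0.30 in wild types (SD, n = 4). Members of the copine family, calcium-dependent phospholipid-binding proteins, stood on both sides. Cpne9 lay at -0.62 (SE 0.09, adjusted p = 0.057), Cpne7 at 0.56 (SE 0.09, adjusted p = 0.083) and Cpne2 at 0.71 (SE 0.13, adjusted p = 0.083). Dcn, the matrix proteoglycan decorin, was at 0.63 (SE 0.11), Gtsf1, a factor of piRNA silencing in germ cells, at 0.31 (SE 0.06) and the kinase gene Sgk1 at -0.31 (SE 0.05), each with an adjusted p of 0.083. The values of these 7 genes did not overlap between genotypes. Where a gene's value was the mean of 2 probe sets, these differed in size. They gave 1.11 and 0.15 for Dcn, 0.46 and 0.17 for Gtsf1 and 0.78 and 0.34 for Cpne7. Over the alternative settings Dcn ranged from 0.39 to 1.11.

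**Figure D1:**
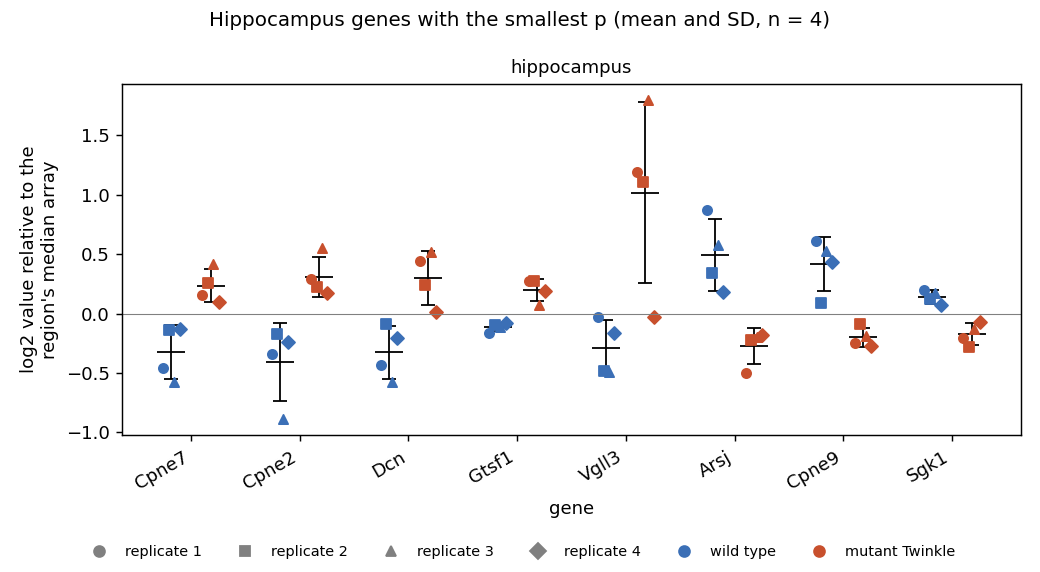
Values of 8 hippocampus genes on each array, in log2 units relative to the median array of the region, with points for wild-type and mutant replicates and bars for the mean ± SD of 4 arrays. Cpne7, Cpne2, Dcn and Gtsf1 lie above 0 in every mutant, Arsj, Cpne9 and Sgk1 lie below 0 in every mutant, and Vgll3 has 1 mutant array at -0.03.

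Farther down, Vgll3, a cofactor of TEAD transcription factors, was at 1.31 (SE 0.24, adjusted p = 0.12) and Trhr, the receptor of thyrotropin-releasing hormone, at 1.02 (SE 0.21, adjusted p = 0.16). The Wnt regulator Nkd2 lay at 0.42 and Meig1 at 0.43. Alas2 was at -1.19 (SE 0.24, adjusted p = 0.16), with -0.39 ± 0.18 in mutants and 0.80 ± 0.60 in wild types (SD, n = 4). The potassium channel partner Kcnip4 and the endocannabinoid-synthesising lipase Dagla lay at -0.33 each, and the prostaglandin synthase Ptgs2 at -0.69 (adjusted p = 0.23). ND5, the only one of 13 listed mitochondrially encoded genes that was measured, lay at -0.23 (SE 0.06, adjusted p = 0.43), with -0.16 ± 0.08 in mutants and 0.06 ± 0.02 in wild types (SD, n = 4). In the cerebellum ND5 was at -0.07 (SE 0.06, adjusted p = 0.93).

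limma called 0 of 18168 genes in the hippocampus. At an unadjusted p under 0.05 there were 1459, against 908.4 by chance, and the smallest adjusted p was 0.0571. Mutants and wild types lay apart for 864 genes, or 4.76%, where chance gives 2.86%. The count depended on the setting. Quantile normalization of the centred values, which gives every array the same spread, called 4 genes, Arsj, Cpne9, Cpne2 and Cpne7. The SD of an array's values was 0.261 on wild-type replicate 1 and at most 0.161 on the other hippocampus arrays. The main fit called 7 genes without wild-type replicate 2, 3 without wild-type replicate 4 (Ptgs2, Arsj and Cpne7), 2 without mutant replicate 4 (Vgll3 and Dcn) and 1 without mutant replicate 1 (Cfap161, outside the naming rule). Other settings went the opposite way and left no gene under an adjusted p of 0.1. The smallest adjusted p was 0.644 with the 8 hippocampus arrays fitted alone, 0.148 with every probe set tested on its own and 0.136 with the replicate set as a term. It was 0.139 without mutant replicate 2, 0.126 without mutant replicate 3, 0.231 without wild-type replicate 3 and 0.177 without the 3 arrays with raised granule neuron genes.

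Ependymal genes had the largest mean difference of the 42 lists in the hippocampus. The list holds genes of the ciliated cells that line the ventricles. Its mean was 0.31 ± 0.24 in mutants and -0.13 ± 0.13 in wild types (SD, n = 4), a difference of 0.44 with 12 of 14 members above 0 (camera adjusted p = 2.3e-09; adjusted p = 0.42 with an estimated correlation). Tmem212 lay at 1.06, the adenylate kinase Ak7 at 0.65 and Meig1 at 0.43. Adjusted over the list alone, 10 of the 14 members passed, all higher, and over all genes 0 did. Leaving out single arrays gave means from 0.37 to 0.54, with the camera call made in 8 of 8 fits. The list was highest on mutant replicates 3 and 4, at 0.47 and 0.52. Both are among the 5 hippocampus arrays with raised markers of other tissue, and replicate 4 stood at 1.54 for choroid plexus genes. Mutant replicate 2 stood at 0.24, and mutant replicate 1, at -0.00, lay next to wild-type replicate 2, at -0.01.

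Inhibitory interneuron genes also lay higher, by 0.14 on average with 14 of 17 members above 0 (camera adjusted p = 4e-04; adjusted p = 0.091 with an estimated correlation). The list had 0.07 ± 0.04 in mutants and -0.06 ± 0.09 in wild types (SD, n = 4), and it was the 1 list that fry called in this region (fry adjusted p = 0.012). Adjusted over the list alone, 7 members passed, all higher. Among them were the serotonin receptor Htr3a at 0.26, the neuropeptide Cort at 0.25 and the transcription factor Dlx2 at 0.19. The call was made in 8 of 8 fits with 1 array left out, with means from 0.09, without wild-type replicate 3, to 0.16. The mean was 0.08 (camera adjusted p = 0.38) without the 5 arrays with raised markers of other tissue.

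Other lists higher in mutant hippocampus rested more on single arrays. Meningeal and fibroblast genes averaged 0.35 with 19 of 19 above 0, among them Dcn, Lum at 0.65 and Fbln1 at 0.31, which passed when adjusted over the list alone (camera adjusted p = 6.6e-05; adjusted p = 0.77 with an estimated correlation). Mutant replicate 1 alone stood at 1.10 for this list, and without it the mean was 0.07 and Fbln1 was at 0.18. Lum was at 0.39 without wild-type replicate 1. Choroid plexus genes averaged 0.30 (camera adjusted p = 0.039; adjusted p = 0.8 with an estimated correlation), with mutant replicate 4 at 1.54 and a mean of -0.09 without it. That call was also lost without wild-type replicate 3, at 0.21, or 4, at 0.17. Oligodendrocyte and myelin genes averaged 0.14 with 20 of 21 above 0 and Ndrg1 at 0.31 (camera adjusted p = 0.00084; adjusted p = 0.77 with an estimated correlation). Their mean was 0.09 and no longer passed without wild-type replicate 4. Complex I subunits averaged 0.04 (camera adjusted p = 0.046; adjusted p = 0.8 with an estimated correlation), a call made in 2 of 8 fits with 1 array left out. It was kept only without mutant replicate 1 or 2, and the other 6 fits gave means from 0.03 to 0.05.

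Immediate early genes, which neurons switch on within minutes of activity, lay lower in mutant hippocampus by -0.24 on average, with 19 of 25 below 0, Egr3 at -0.41 and Ier5 at -0.69 (camera adjusted p = 4e-04; adjusted p = 0.77 with an estimated correlation). Wild-type replicate 2 stood at 0.78 for this list, and without it the mean was -0.05 and the call was lost. Without wild-type replicate 1, Egr3 was at -0.26 and Ier5 at -0.36. Dentate granule neuron genes averaged -0.10, with Prox1 at -0.39 and Lct at -0.51 (camera adjusted p = 0.0062; adjusted p = 0.42 with an estimated correlation). Their mean was -0.05 without wild-type replicate 3, where the call was lost and Lct was at -0.26. Blood cell genes averaged -0.21 (camera adjusted p = 0.0083; adjusted p = 0.77 with an estimated correlation). Their mean was -0.05, and the call was lost, without wild-type replicate 3, which stood at 0.65. Adjusted over the list alone, Alas2 and Hbb-b2 passed, both lower. Regulators of mitochondrial biogenesis averaged -0.07, with Prkaa2, a catalytic subunit of the energy sensor AMPK, at -0.22 and passing when adjusted over the list alone (camera adjusted p = 0.014; adjusted p = 0.42 with an estimated correlation). This call was lost without wild-type replicate 1, at -0.05, or mutant replicate 4, at -0.06. Circadian clock genes averaged -0.08 with Cry1 at -0.37 (camera adjusted p = 0.016; adjusted p = 0.42 with an estimated correlation), and the call was lost without mutant replicate 2, at -0.05, wild-type replicate 2, at -0.06, or mutant replicate 3, at -0.07. Cry1 was at -0.14 without wild-type replicate 1.

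Genes of cerebellar neurons were part of the hippocampus lists too. Purkinje cell genes averaged -0.13 and cerebellar granule neuron genes -0.15 (camera adjusted p = 0.011 for each; adjusted p = 0.77 with an estimated correlation for each). Wild-type replicate 1 stood at 0.90 and 1.50 for these lists, and without it the means were 0.11 and 0.26. The Purkinje call was also lost without mutant replicate 4, at -0.11, and the granule neuron call without mutant replicate 4, at -0.09, or 2, at -0.07. The stress response of amino acid and one-carbon metabolism averaged 0.04 over 27 genes (camera adjusted p = 0.58), and its arginine transporter Slc7a3, at 0.59 (SE 0.14), passed when adjusted over the list alone. In the glucocorticoid-responsive list, which averaged 0.01, Sgk1 passed when adjusted over the list alone. The other 29 lists had means between -0.08 and 0.07. With an estimated correlation 0 of the 42 lists passed, and other divisions of the 8 arrays into 4 and 4 called a median of 12 lists and up to 21, against 13 here.

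**Figure D2:**
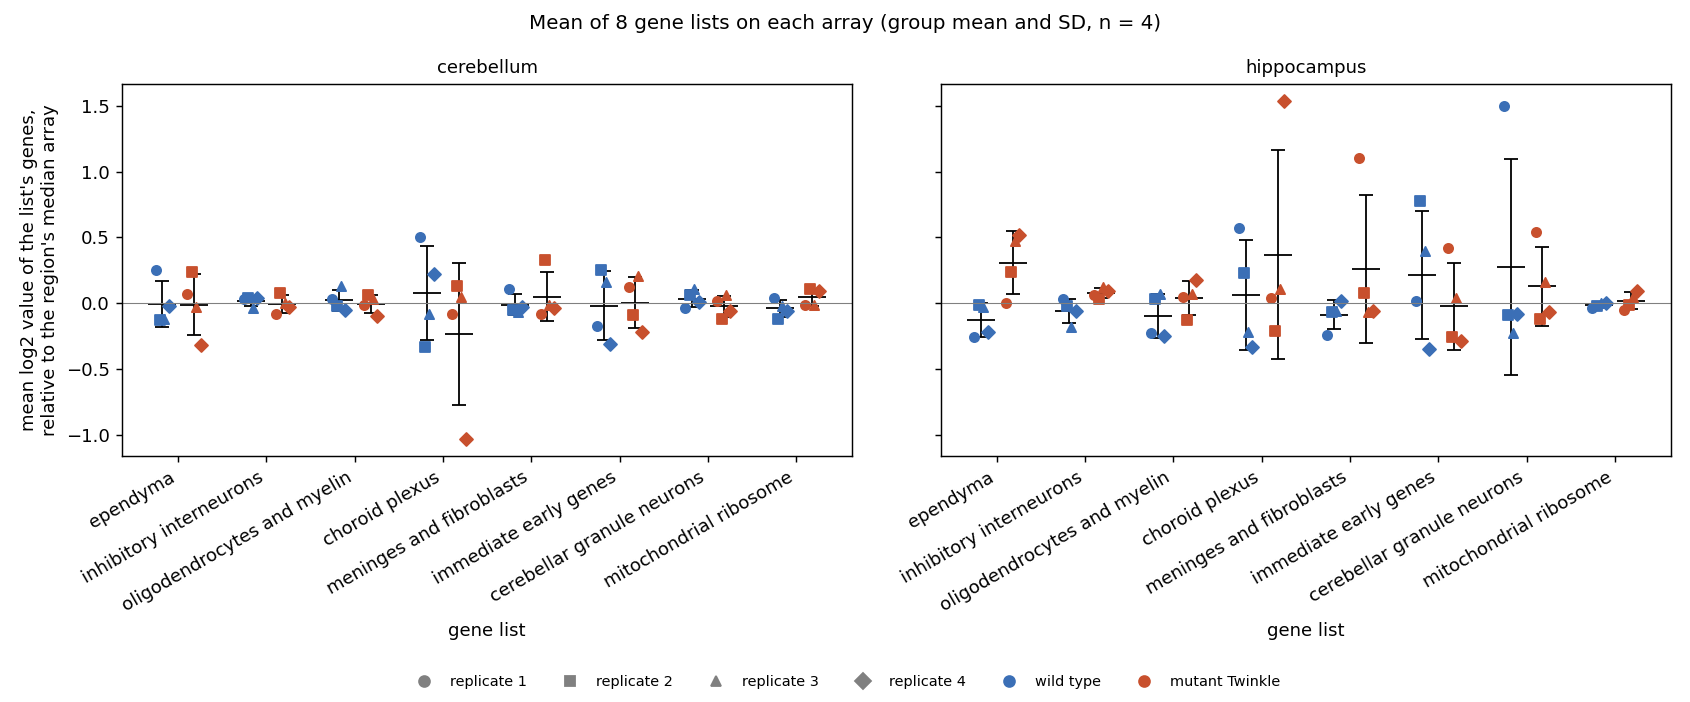
Mean log2 value of 8 gene lists on each array, relative to the median array of the region, for cerebellum and hippocampus, with bars for the group mean ± SD of 4 arrays. Ependymal genes lie between -0.26 and -0.01 in wild-type hippocampus and between -0.00 and 0.52 in mutant hippocampus, while single arrays stand apart for choroid plexus, meninges and granule neurons.

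The difference of the genotype effect between regions, hippocampus minus cerebellum, had the genes of smallest p in Gm10710 at 0.54, Nrbp2 at 0.42, Leo1 at -0.38 and Arsj at -0.79 (SE 0.16), each with an adjusted p of 0.67. Cpne9 was at -0.61 and Cpne2 at 0.75 (SE 0.18), with adjusted p of 0.72 and 0.87. None passed. Among lists, inhibitory interneurons differed by 0.16 with 14 of 17 members above 0 (camera adjusted p = 0.00042; adjusted p = 0.083 with an estimated correlation; fry adjusted p = 0.036). Ependymal genes differed by 0.44, choroid plexus genes by 0.61, meningeal genes by 0.29, oligodendrocyte genes by 0.16, immediate early genes by -0.26, microglial genes by -0.17 and the mitochondrial ribosome by -0.05, each passing with camera, and each at adjusted p = 0.98 with an estimated correlation. With 1 of the 16 arrays left out, the interneuron and ependymal calls were made in 16 of 16 fits, and the 8 lists became 14 without wild-type hippocampus replicate 1. The choroid plexus difference was 0.22 and no longer passed without mutant hippocampus replicate 4, and the oligodendrocyte difference was 0.11 and no longer passed without wild-type hippocampus replicate 4. The meningeal difference was 0.01 without mutant hippocampus replicate 1, and its call was also lost without mutant cerebellum replicate 3, at 0.27. The microglial call was lost without wild-type hippocampus replicate 1, at -0.06, mutant cerebellum replicate 2, at -0.09, or mutant hippocampus replicate 3, at -0.11. The call of the mitochondrial ribosome was lost without mutant cerebellum replicate 2 or 4, wild-type cerebellum replicate 2 or mutant hippocampus replicate 1, at -0.03 to -0.02. That of immediate early genes was lost without wild-type hippocampus replicate 2, at -0.07, and without mutant hippocampus replicate 2 or 4, mutant cerebellum replicate 1 or 3 or wild-type cerebellum replicate 1 or 4, at -0.22 to -0.16. limma called 0 genes, with 972 at an unadjusted p under 0.05 and a smallest adjusted p of 0.671. Without mutant hippocampus replicate 4 the fit called 1 gene, Vgll3 at 1.61, and without wild-type hippocampus replicate 4 it called 1, Ptgs2 at -0.93, both outside the naming rule for this comparison.

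Averaged over both regions, the genes of smallest p higher in mutants were Gstt1, a glutathione transferase, at 0.25 (SE 0.04), and Ak7, a kinase of motile cilia, at 0.40 (SE 0.06). Dnajb13, a component of ciliary axonemes, was at 0.22 and Ccdc153 at 0.34. Gtsf1 was at 0.22 and Cpne2 at 0.34. Lower were Alas2 at -1.08 (SE 0.21), Jmjd1c at -0.24, Sgk1 at -0.21, Arsj at -0.37 and Tent5c at -0.37. Each had an adjusted p of 0.51, so none passed. The average hides unlike regions for some of these genes. Ccdc153 lay at -0.02 in the cerebellum and 0.70 in the hippocampus, Cpne2 at -0.03 and 0.71, and Arsj at 0.03 and -0.77. Gstt1, at 0.19 and 0.31, Dnajb13, at 0.24 and 0.19, and Alas2, at -0.97 and -1.19, moved the same way in both. limma called 0 genes, with 1546 at an unadjusted p under 0.05 and a smallest adjusted p of 0.511. Across genes, which are not independent replicates, the log2 differences of both regions correlated with a Pearson r of 0.07. Of the 200 genes of smallest p in the cerebellum, 115 had the same sign in the hippocampus, and of the 200 of smallest p in the hippocampus, 109 had the same sign in the cerebellum. Camera called 13 lists, 5 higher and 8 lower in mutants, and with an estimated correlation 0 passed. Ependymal genes averaged 0.22, from 0.44 in the hippocampus and -0.01 in the cerebellum, where 7 of 14 members were above 0 (camera adjusted p = 0.99). The averaged list passed (camera adjusted p = 1.3e-08; adjusted p = 0.41 with an estimated correlation), with 9 of 14 members passing when adjusted over the list alone. Meningeal genes averaged 0.21 (camera adjusted p = 0.00023; adjusted p = 0.55 with an estimated correlation), and 0.09, no longer passing, without mutant replicate 1. Complex I averaged 0.05 and fatty acid oxidation genes 0.06 (camera adjusted p = 0.00024 and 0.0056; adjusted p = 0.55 and 0.45 with an estimated correlation). The mitochondrial ribosome averaged 0.06 with 64 of 65 above 0 (camera adjusted p = 4.5e-06; adjusted p = 0.57 with an estimated correlation), and 0.04 without mutant replicate 4. Circadian clock genes averaged -0.09 with 14 of 16 below 0, synaptic genes -0.06 and glycolysis genes -0.04 (camera adjusted p = 0.00023, 0.00068 and 0.0046; adjusted p = 0.41, 0.55 and 0.43 with an estimated correlation). The synaptic mean was -0.03 without wild-type replicate 3, -0.04 without wild-type replicate 4 and -0.10 without wild-type replicate 1. Dentate granule neuron genes averaged -0.07, and -0.04 without wild-type replicate 3 (camera adjusted p = 0.0037; adjusted p = 0.5 with an estimated correlation). Purkinje cell genes averaged -0.09 and cerebellar granule neuron genes -0.11 (camera adjusted p = 0.0012 and 0.0034; adjusted p = 0.55 and 0.57 with an estimated correlation), and both calls were lost without wild-type replicate 1, at 0.01 and 0.09. The granule neuron mean was -0.18 without mutant replicate 1 or wild-type replicate 3, -0.17 without wild-type replicate 4, -0.07 without mutant replicate 4 and -0.05 without mutant replicate 2. Immediate early genes averaged -0.11 (camera adjusted p = 0.0056; adjusted p = 0.76 with an estimated correlation), a call lost without wild-type replicate 2, at 0.03, mutant replicate 4, at -0.03, mutant replicate 2, at -0.05, or wild-type replicate 3, at -0.05. Their mean was -0.25 without wild-type replicate 4 and -0.20 without mutant replicate 1. Regulators of mitochondrial biogenesis averaged -0.04 (camera adjusted p = 0.02; adjusted p = 0.41 with an estimated correlation), a call lost without mutant replicate 1, at -0.04, or wild-type replicate 3, at -0.03. fry called 1 list, complex IV, with 11 of 11 subunits above 0 and a mean of 0.05 (fry adjusted p = 0.031; camera adjusted p = 0.06; adjusted p = 0.5 with an estimated correlation).

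Alas2 was accompanied by adult globin signals. These were 4 probe sets, picked after their values had been seen because each is annotated to several adult globin genes and so was not part of the gene tests. In both regions the 4 mutants lay below the 4 wild types on each of them. Their mean was -0.30 ± 0.16 in mutant and 0.27 ± 0.13 in wild-type cerebellum (SD, n = 4), a difference of -0.57. In the hippocampus it was -0.19 ± 0.14 and 0.47 ± 0.35 (SD, n = 4), a difference of -0.66. No p is given, since the probe sets were picked with these values in view. Other globin probe sets with 1 symbol, looked at afterwards too, did not all follow. The pair for Hbb-b2 gave -0.61 and -0.15 in the cerebellum and -1.02 and -0.17 in the hippocampus. The probe set for Hba-a2 gave 0.09 in the cerebellum and 0.17 in the hippocampus, and that for Hba-a1 gave -0.02 and 0.08.

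**Figure D3:**
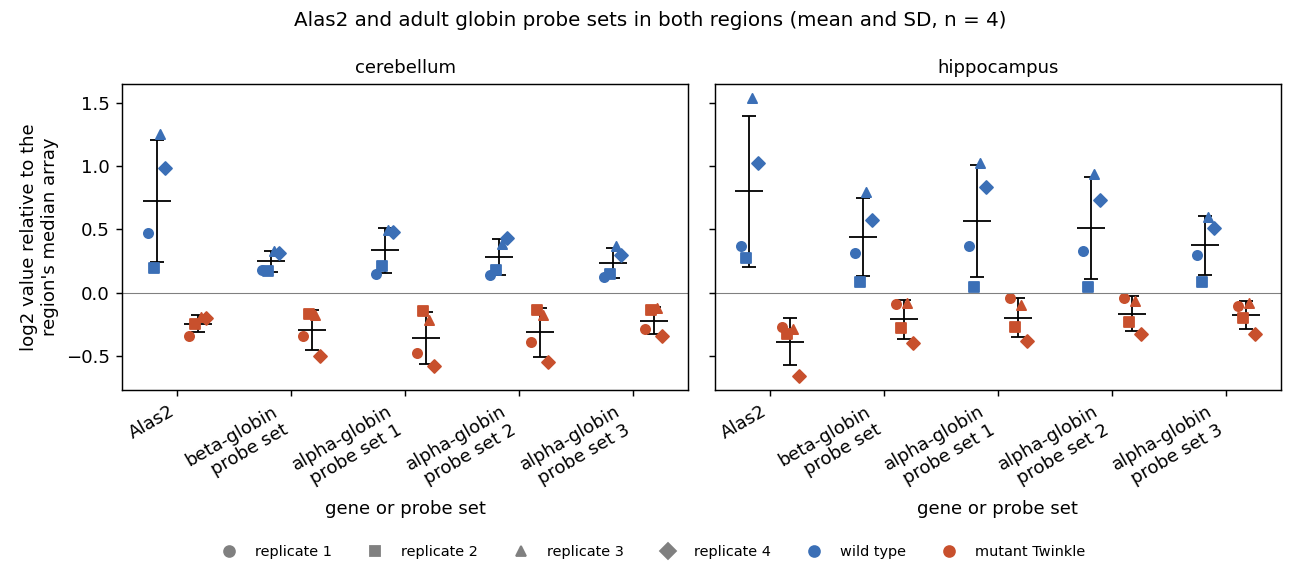
Values of Alas2 and of 4 probe sets shared by adult globin genes on each array, in log2 units relative to the median array of the region, with bars for the mean ± SD of 4 arrays. In both regions every mutant array lies below 0 and every wild-type array above 0.

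Microglial genes differed between the replicate numbers, which go with age. Replicates 1 and 2 of both genotypes were 24 months or older, and replicates 3 and 4 were 23 months or younger. The microglial list had 0.16 ± 0.11 in replicates 1 and 2 and -0.13 ± 0.05 in replicates 3 and 4 of the cerebellum (SD, n = 4; exact permutation p = 0.0286, two-sided). In the hippocampus the means were 0.18 ± 0.14 and -0.17 ± 0.04 (SD, n = 4; exact permutation p = 0.0286, two-sided). This p is the smallest that 4 against 4 can give, for 1 of 42 lists singled out after its values had been seen. With genotype in the model, the list was higher in replicates 1 and 2 by 0.29 in the cerebellum, with 25 of 26 members above 0 (camera adjusted p = 1.6e-21; adjusted p = 0.055 with an estimated correlation). In the hippocampus it was higher by 0.34, with 23 of 26 above 0 (camera adjusted p = 2.3e-20; adjusted p = 0.042 with an estimated correlation). Complement and inflammatory genes were higher by 0.29 in the hippocampus (camera adjusted p = 7.3e-13; adjusted p = 0.042 with an estimated correlation) and by 0.12 in the cerebellum (camera adjusted p = 0.0016; adjusted p = 0.35 with an estimated correlation). With 1 array left out, the microglial difference lay between 0.25 and 0.33 in the cerebellum and between 0.28 and 0.38 in the hippocampus, passing in 8 of 8 fits each. The genotypes differed less for microglial genes, by 0.09 in the cerebellum and -0.08 in the hippocampus (camera adjusted p = 0.055 and 0.061). limma called 0 genes between the sets in each region, with 764 and 1190 at an unadjusted p under 0.05. In the average of both regions it called 2, both outside the naming rule, the matrix protein gene Postn at 0.49 (adjusted p = 0.031) and the macrophage elastase Mmp12 at 0.65 (adjusted p = 0.031).

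Other lists differed between the replicate sets, some passing with camera in 1 region only. Whether a list's difference was unlike in both regions was not tested list by list. Reactive astrocyte genes were higher in replicates 1 and 2 by 0.39 in the hippocampus, with 19 of 19 above 0 (camera adjusted p = 7.2e-15; adjusted p = 0.067 with an estimated correlation), and by 0.24 without wild-type replicate 1. In the cerebellum they were higher by 0.17 (camera adjusted p = 2.6e-05; adjusted p = 0.35 with an estimated correlation). Interferon-stimulated genes were higher by 0.11 in the cerebellum, with 25 of 27 above 0, and by 0.05 without wild-type replicate 1 and 0.17 without wild-type replicate 2, and by 0.14 in the hippocampus, with 21 of 27 above 0. The mitochondrial ribosome was lower by -0.06 in the hippocampus and at 0.01 in the cerebellum (camera adjusted p = 5.5e-06 and 0.81). Ependymal genes were higher by 0.23 in the cerebellum, and by 0.15 without mutant replicate 4, and differed by -0.19 in the hippocampus, where the call was lost without mutant replicate 1, at -0.11. Heat shock and endoplasmic reticulum chaperones were lower by -0.12 in the cerebellum, and by -0.07 without wild-type replicate 3. Choroid plexus genes were higher by 0.27 in the cerebellum with 22 of 22 above 0, but by 0.00 without mutant replicate 4, and the call was also lost without mutant replicate 1, at 0.26, mutant replicate 2, at 0.18, or wild-type replicate 1, at 0.15. In the hippocampus, cerebellar granule neuron genes were higher by 0.51 and Purkinje cell genes by 0.30, and by 0.13 and 0.07 without wild-type replicate 1, which ended the granule neuron call. Meningeal genes were higher by 0.26, and at -0.02 without mutant replicate 1. Immediate early genes were higher by 0.29, a call lost at 0.12 without wild-type replicate 2 or 4. Dentate granule neuron genes were lower by -0.14, and by -0.09 without wild-type replicate 1. In the region given, each of these lists passed with camera at the preset correlation and none with an estimated correlation. In the other region, choroid plexus, granule neuron, Purkinje cell, meningeal, immediate early and dentate granule neuron genes did not pass with camera (adjusted p between 0.33 and 0.81). Other lists also passed with camera, but each of those calls ended without at least 1 array. These were astrocytes, endothelium, pyramidal neurons, oligodendrocytes, glycolysis, complex I, ATP synthase, mitochondrial chaperones and heat shock genes in the hippocampus, and cholesterol synthesis and mitochondrial biogenesis regulators in the cerebellum. Oligodendrocyte genes differed by 0.02 in the cerebellum and -0.09 in the hippocampus.

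**Figure D4:**
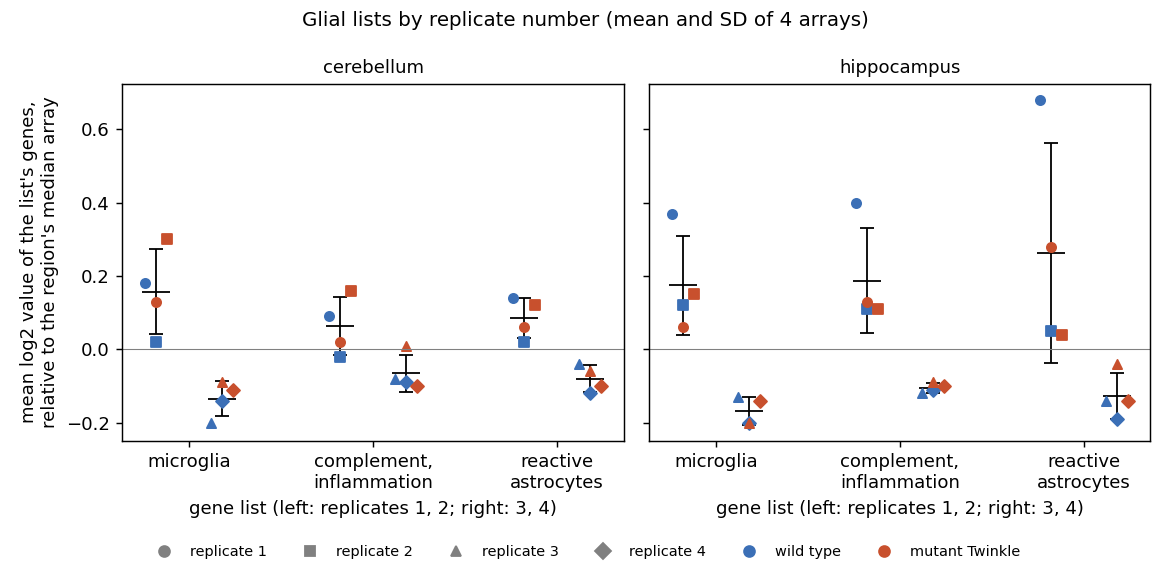
Mean log2 value of 3 glial gene lists on each array, relative to the median array of the region, with replicates 1 and 2 on the left and 3 and 4 on the right of each list and bars for the mean ± SD of 4 arrays. For the microglial list, every array of replicates 1 and 2 lies above every array of replicates 3 and 4 in both regions.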

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

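The tests on wild-type hippocampus replicate 1 and the comparison of the mitochondrial ribosome between regions were chosen only after the results had been seen, as were leaving out the arrays with raised markers or shifted spike-in probe sets and leaving out single arrays in the differences of lists between regions.

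Wild-type hippocampus replicate 1 stood far above the other wild types for genes of cerebellar neurons, at 1.50 for granule neurons (others -0.23 to -0.08) and 0.90 for Purkinje cells (others -0.11 to -0.03), while hippocampal pyramidal neuron genes were at -0.47. An exchange with a cerebellum sample is argued against, because the lowest granule neuron mean among the 8 cerebellum arrays was -0.12. Cerebellar RNA in this hippocampus sample is a candidate explanation, since Purkinje and granule neuron genes ranked alike on this array and on mutant hippocampus replicate 1, where granule neuron genes stood at 0.54 (rank correlation 0.69, against at most 0.47 for any other pair of hippocampus arrays). Genes of reactive astrocytes (0.68), complement (0.40) and microglia (0.37) were high on the same array, with Socs3, a feedback inhibitor of cytokine signalling, at 2.25. Whether cerebellar tissue brought these too cannot be told apart from a reaction in this animal, because the other arrays with raised granule neuron genes differed. On mutant replicate 1 the lists stood above 0, at 0.28 for reactive astrocytes, 0.13 for complement and 0.06 for microglia. That array belongs to the replicates in which microglial genes were higher. On mutant replicate 3, where granule neuron genes stood at 0.16, 0 of the 3 lists were above 0, at -0.04, -0.09 and -0.20 against 0.07, 0.04 and 0.04 in proportion, a gap beyond the SD of the other arrays for complement (0.12) and microglia (0.15) but not for reactive astrocytes (0.18), on an array of the replicates in which microglial genes were lower.

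The mitochondrial ribosome list, higher by 0.08 in mutant cerebellum, had a genotype effect lower by -0.05 in the hippocampus than in the cerebellum. On the cerebellum arrays, the poly-A spike-in probe sets, which take no part in the comparisons of genes, stood at 0.62 and 0.65 on mutant replicates 2 and 4, above the wild-type arrays of the cerebellum (at most 0.05). With their mean as a covariate, the list's difference went from 0.08 to 0.03, a share of 0.32. The covariate was high only on mutant arrays, so its effect cannot be fully told apart from genotype. A uniform shift of whole arrays is argued against by the medians of mutant replicates 2 and 4, which were 0 and -0.00587. All 7 list calls were kept with each array centred on its median. This does not count against a shift, since camera compares a list with the other genes of the same arrays. An effect that goes with the poly-A spike-ins but is not uniform stays open. A shift seen in the hybridization spike-in probe sets, at -0.724 on wild-type replicate 4, is argued against, because with their mean as a covariate the share was 0.94. A change that goes with the genotype in both regions stays open, because the difference in the hippocampus was 0.44 of that in the cerebellum, a share that decides neither way. No error of this share was computed.

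Other gene lists differed between regions in their genotype effect with camera at the preset correlation. The differences, hippocampus minus cerebellum, were 0.44 for ependyma, 0.61 for choroid plexus, 0.29 for meninges, 0.16 for inhibitory interneurons, 0.16 for oligodendrocytes, -0.26 for immediate early genes and -0.17 for microglia. With an estimated correlation 0 of them passed, at adjusted p = 0.083 for interneurons and 0.98 for the others. Single arrays carried several. The meningeal difference was 0.01 without mutant hippocampus replicate 1, that of immediate early genes -0.07 without wild-type hippocampus replicate 2, that of microglia -0.06 without wild-type hippocampus replicate 1 and that of choroid plexus 0.22 without mutant hippocampus replicate 4.

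Of 188 groups of 4 arrays, 15 had an array far from the others, where chance gives 1 in 20, or 9.4. Beside the Purkinje and granule neuron lists, wild-type hippocampus replicate 1 stood apart for regulators of mitochondrial biogenesis, at 0.11 (others 0.01 to 0.03). Mutant hippocampus replicate 1 stood at 1.10 for meningeal genes (others -0.07 to 0.08) and at -0.50 for Arsj (others -0.22 to -0.18). Mutant hippocampus replicate 2 stood at 0.06 for synaptic genes (others -0.06 to -0.04) and at -0.05 for ND5 (others -0.21 to -0.19). Mutant hippocampus replicate 3 stood at 0.04 for dentate granule neuron genes (others -0.11 to -0.08) and at -0.03 for Foxn2 (others -0.27 to -0.23). Mutant hippocampus replicate 4 stood at -0.66 for Alas2 (others -0.33 to -0.27). Wild-type hippocampus replicate 3 stood at 0.65 for blood cell genes (others -0.02 to 0.07). In the cerebellum, mutant replicate 2 stood at 0.33 for meningeal genes (others -0.08 to -0.01) and mutant replicate 4 at -0.05 for dentate granule neuron genes (others -0.01). Wild-type cerebellum replicate 2 stood at -0.15 for Twnk (others -0.01 to 0.01) and wild-type cerebellum replicate 3 at -0.04 for interneuron genes (others 0.03 to 0.04).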

How the results depend on the processing

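The largest-spread probe set, the filter on spread, the probe sets with empty values, the removal of several arrays at once, median centring for lists and all settings for lists in the difference, the average and the replicate sets were chosen after the data had been seen. The cerebellum count of 0 genes stayed at 0 in every setting. The hippocampus count of 0 became 4 with quantile normalization, 6 without the 40% of genes of smallest spread, where fewer genes share the adjustment, and 6 without the 5 arrays with raised markers of other tissue, where the lone mutant replicate 2 is assumed to vary like the other groups. Leaving out single replicates gave 0 to 7 in the hippocampus and 0 to 1 in the difference between regions, which had 2 without those 5 arrays. The average over regions had 1 with every probe set tested on its own. With age as a covariate 0 genes were called in each comparison. Genes at an unadjusted p under 0.05 then numbered 1305 in the cerebellum, 1616 in the hippocampus, 1040 in the difference and 2008 in the average. Without it they numbered 979, 1459, 972 and 1546. The lists called in the cerebellum went from 7 to 0 with an estimated correlation, 0 with fry and 0 without mutant replicates 2 and 4. Those in the hippocampus went from 13 to 0 with an estimated correlation, 1 with fry and 8 without the 5 arrays, with a range of 8 to 17 over single replicates. In the difference between regions 8 lists became 0 with an estimated correlation, 1 with fry and 6 to 14 over single replicates, and in the average 13 became 0 and 1.

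Reversed means in the hippocampus, without the 5 arrays, were -0.00 for complex I, 0.04 for Purkinje cells, 0.19 for microglia, -0.02 for oligodendrocytes and -0.16 for choroid plexus. Without the 3 arrays with raised granule neuron genes the mean was 0.05 for Purkinje cells. Over single replicates the ranges were -0.23 to 0.11 for Purkinje cells, -0.32 to 0.26 for granule neurons, -0.17 to 0.12 for reactive astrocytes and -0.09 to 0.50 for choroid plexus. In the difference they were -0.18 to 0.16 for Purkinje cells and -0.26 to 0.32 for granule neurons, and in the average -0.10 to 0.09 for reactive astrocytes, -0.06 to 0.10 for microglia and -0.08 to 0.15 for choroid plexus. Between replicate sets choroid plexus ranged from -0.34 to 0.33 in the hippocampus. For meninges camera's direction turned while the mean stayed positive, at 0.05 without the 3 arrays, and at 0.07 to 0.46 in the hippocampus and 0.01 to 0.40 in the difference over single replicates. Beyond the removal of arrays, the cause was not tested. Of the settings for single named genes, 7045 gave the same result, 57 moved and 21 passed the threshold.

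The replicate numbers did not pair the samples of both genotypes. Correlations of same-numbered deviations ranged from -0.19 to 0.05 in the cerebellum and from -0.07 to 0.23 in the hippocampus, and 0 and 1 of 4 samples were closest to their own number. Between the regions, whose equal numbers the average joins, they ranged from -0.17 to 0.13 in mutants and -0.05 to 0.17 in wild types, with 2 and 1 of 4 closest to their own number and a consensus correlation of -0.057, so the data did not show that equal numbers share an animal. With the number as a replicate block, gene counts stayed at 0, with a smallest adjusted p of 0.33 in the hippocampus, and 8 and 13 lists were called. A pseudocount, filters on dim probe sets and comparisons between tissues could not be run on centred values.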

Other observations

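The tests on the microglial list between replicate sets were chosen only after the results had been seen; the divisions of the samples were fixed before.

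Mutants and wild types lay fully apart in both regions, in the same direction, for 15 genes, 10 higher and 5 lower in mutants. As many, 15, lay apart in opposite directions, and 10.6 in the same direction would follow if the regions were independent. These genes were chosen after their values had been seen. Beside Alas2 and the glutathione transferase Gstt1, at 0.19 in the cerebellum and 0.31 in the hippocampus, they included Uros, another enzyme of haem synthesis, higher in mutants at 0.09 and 0.16. Micos13, a subunit of the complex that shapes mitochondrial cristae, was at 0.08 and 0.07. Nptx1, neuronal pentraxin, was lower at -0.15 and -0.21, and Eef2k, the kinase of elongation factor 2, at -0.11 and -0.13. Their adjusted p in the average over regions was 0.51 to 0.6. Of the sex-linked genes, a check outside the naming rule, Xist, Eif2s3y, Kdm5d and Uty stayed between -0.30 and 0.30 over all 16 arrays. Spink8, a hippocampal pyramidal neuron gene, stood at 3.24 on mutant cerebellum replicate 2 and at most at 0.60 on the other cerebellum arrays. The pyramidal neuron list, which includes Spink8, stood at 0.27 on that array and between -0.05 and 0.06 on the other cerebellum arrays. Tissue from outside the cerebellum was not tested as a source.

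The microglial list was higher in replicates 1 and 2. In the average of both regions, Cd68, picked after its value had been seen, was higher there by 0.76 (adjusted p = 0.063), but did not pass. Foreign tissue stays open, since the count run for it, 8 of 8 arrays of replicates 1 and 2 above all arrays of 3 and 4 of their region, only restates the pattern. Age may be the source and cannot be told apart from processing in separate batches, since the older animal had the higher list mean in 3 of the 4 wild-type pairs of unequal age, and the sets differed in 764 genes at an unadjusted p under 0.05 in the cerebellum but 1190 in the hippocampus, against 908.4 by chance. Of the 18 divisions of the replicate numbers within genotype, 1 gave the 2 genes called here, with 0 as the highest of the others, too few divisions for a share under 0.05.

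The 35 divisions of 8 samples into 4 and 4 were run for each comparison. In the hippocampus, 1 of 35 gave as many genes at an unadjusted p under 0.05 (the real 1459, with 1456 as the highest other). This share is under 0.05 but is the smallest that 35 divisions can give, and the lead is 3 genes. Chance is not excluded for this count, as 1 of 8 such counts, nor for the others. As many genes came from 13 of 35 in the cerebellum (979, highest other 2104), 11 of 35 in the difference between regions (972, highest other 2120) and 2 of 35 in the average (1546, highest other 1548). In the cerebellum and the difference, the highest counts were over 2 times the real ones, which points to a structure of the samples. Both of these divisions kept mutants 1, 2 and 4 together, and what the structure is was not tested. As many lists came from 11 of 35 in the cerebellum (7, highest other 12), 17 of 35 in the hippocampus (13, highest other 21), 21 of 35 in the difference (8, highest other 14) and 11 of 35 in the average (13, highest other 18). The division into replicates 1 and 2 against 3 and 4 called 9 lists in the cerebellum, 21 in the hippocampus, 9 in the difference and 16 in the average, as many as genotype or more.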
